A study of Mus musculus with 4 samples.

How the data were processed

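Bone marrow cells of wild-type mice and of mice lacking GM1082 were given M-CSF, the cytokine that drives bone marrow progenitors towards macrophages, for 5 days. Total RNA of 2 libraries per genotype was sequenced from standard Illumina libraries, per the labels. The 4 libraries were named by genotype and by the replicate number in their titles. The labels give no batch, date, sex or strain, and do not say whether the 2 libraries of a genotype came from separate animals, so p-values here measure only the spread between these samples, which may be technical.

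The deposited table gives FPKM values (fragments scaled to gene length and to the mapped fragments of the library) made by the authors for 62046 rows. Of these, 21500 carry Ensembl mouse gene identifiers with a symbol, and 40546 carry NONCODE identifiers, no symbol and the description lncRNA, per the file headers. Bowtie 0.12.2 and the genome build mm9 are named in the submitters' processing notes, while the tool that assigned reads to genes, the handling of strand and the treatment of reads with several matches are not given in the sources used here. The coordinates in the table were compared with RefSeq positions on GRCm38. Of 18848 rows matched by Entrez number, 99.9% had the same chromosome, 87.4% a start within 1 kb and 86.8% an end within 1 kb. Coordinates below are those of the table and are read as GRCm38. No row was at 0 in all 4 libraries. Gene identifiers were looked up in a table of Ensembl symbols, in which 21457 were found and 21021 had the same symbol. A row was called mRNA where RefSeq lists its gene as protein coding (16147 rows), lncRNA where the table says so (40546 rows), and other in the remaining 5353 Ensembl rows, which include immunoglobulin segments, pseudogenes and small RNAs.

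FPKM values carry no counts, but the depth could be recovered from the low values. For lncRNA rows spanning 1000 to 3000 bp, FPKM times length fell on multiples of 1 step per library, as whole fragments in genes of 1 exon would. By these steps, 1 FPKM in a gene of 1 kb stood for 19.1 fragments in wild-type replicates 1 and 2, and for 17.7 and 18.1 in knockout replicates 1 and 2. Within 0.05 of a whole multiple lay 82.9% to 83.8% of 5705 to 5912 low values per library. Since exon lengths are not given, fragments were not recovered for all genes and no count model was used. Small RNAs and short segments rest on far fewer. Genes with near-identical copies, such as histones, ribosomal protein pseudogenes, small nuclear and 5S ribosomal RNAs and immunoglobulin variable segments, share reads with those copies, and their values are uncertain. The same holds for overlapping genes and genes on opposite strands.

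Before the data were examined, the test, the gene lists, the rule for named genes and most alternatives were fixed. Rows with a mean of at least 1 FPKM over the 4 libraries (24535 rows) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, giving 4.04 prior degrees of freedom), without a replicate block. P-values were adjusted by the method of Benjamini and Hochberg and read at 0.05. Fold changes are knockout minus wild type on the log2(FPKM + 1) scale, which understates changes of low genes. Each value after ± is an SD over 2 libraries. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so no such test is given.

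In all, 44 gene lists (pathways, macrophage states and markers of other marrow cell types) were fixed. The 43 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Beside it stand camera with a correlation estimated from the residuals and fry. The list of named long noncoding RNAs was matched to rows by position, with a reciprocal overlap of at least 0.9 with the RefSeq gene and without regard to strand. That matching rule was set after the table was seen. The lists were matched by symbol otherwise.

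The rule for named genes took Gm1082, then for each direction the 10 genes with the largest change past the adjusted threshold whose libraries did not overlap between genotypes and whose higher group mean was at least 5 FPKM. Where fewer than 10 passed, it took those and then the genes with the smallest unadjusted p that met the other conditions, said not to have passed. It also took 5 lncRNAs per direction with a higher group mean of at least 1 FPKM, up to 4 members of each list past the threshold and up to 2 of any other list described. Symbols shared by several rows were left out, which concerned 22 symbols. Genes named outside the rule are said to be so.

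Alternatives were a pseudocount of 0.1, filters of 0.1 and 5 FPKM and no filter, median-of-ratios scaling, quantile normalization, eBayes without a trend and with robust variances, the replicate number as a block, each library left out, other thresholds, and for the lists ranks and the other tests named above. A fit of the Ensembl rows alone and of the NONCODE rows alone was added after the data were seen. The gene test was tested on simulated data of 24535 genes with the spread of the real libraries. It called 60% of 50 genes planted at 2-fold, 96% of 50 at 4-fold, 98% of 50 at 8-fold and all of 50 at 16-fold, with 9 false calls. Changes were planted on the log2(FPKM + 1) scale, and only in genes at about 5 FPKM or more. Of the real rows, 10754 had a mean of at least 5 FPKM. Recovery among lower genes was not simulated. All changes were planted in the same simulated data, and the adjusted threshold is looser the more genes change. Where few genes change, as among the 3 real calls, recovery would be lower than these shares. With no planted change it called 0 genes, and 1207 had an unadjusted p below 0.05. The list test called 10 of 10 simulated lists shifted by 0.5 on the log2 scale and 2 of 30 lists that were not shifted. These lists held randomly drawn genes with independent noise. Their false calls therefore do not apply to lists whose members vary together, such as neutrophil markers, with an estimated correlation of 0.77. Figures were drawn with matplotlib 3.10.9.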

Results

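Expression of mRNAs and lncRNAs was compared between macrophage cultures grown from the marrow of wild-type and GM1082 knockout mice, with 2 libraries per genotype. At the depth recovered from the low values, 1 FPKM in a gene of 1 kb stood for 19.1 fragments in both wild-type libraries and for 17.7 and 18.1 fragments in knockout replicates 1 and 2. Between 51247 and 51550 of the 62046 rows were above 0 in a library, and between 24442 and 24564 reached 1 FPKM. The rows described as lncRNA held 17.9% to 19% of summed FPKM per library. The most abundant transcripts by mean level over the 4 libraries were S100a9 (7758 ± 535 FPKM in wild type and 9407 ± 1075 in the knockout, n = 2 each) and S100a8 (7714 ± 181 and 8609 ± 182), the calprotectin subunits abundant in neutrophils and monocytes. These 2 genes and the other genes named in this paragraph were chosen by abundance or as markers after their values were seen. The M-CSF receptor gene Csf1r stood at 119 ± 2.84 FPKM in wild type and 108 ± 6.09 in the knockout, and the macrophage gene Adgre1 at 149 ± 3.73 and 148 ± 13.7.

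The targeted gene was examined first. Gm1082 is a RefSeq synonym of Arhgap33os, a noncoding gene whose start and end equal those of 1 row of the table, NONMMUG078287.1, on chromosome 7 from 30515122 to 30522193 (plus strand). That the label GM1082 means this gene rests on the name alone. Its level was 0.0792 and 0.0198 FPKM in wild-type replicates 1 and 2, and 0.0639 and 0.0624 FPKM in knockout replicates 1 and 2. Corrected for depth, these values stand in the ratio of 4, 1, 3 and 3 fragments, the smallest whole numbers that give them. The group means were 0.0495 ± 0.042 FPKM in wild type and 0.0632 ± 0.00107 FPKM in the knockout (SD, n = 2), far below the filter of 1 FPKM, so the gene was not tested. A loss of the transcript was not detectable at this depth, and the level neither bears out nor contradicts the genotype labels. Of the adjacent genes, Prodh2 on the plus strand (30493622 to 30513402) was listed at 0 in both wild-type libraries and at 0.184 and 0.157 FPKM in the knockout, under the filter and not tested. Arhgap33 on the minus strand (30522226 to 30535060), was at 0.963 and 1.96 FPKM in wild type and 1.61 and 1.23 FPKM in the knockout.

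Between the genotypes, 3 transcripts differed. Igha, the constant region of the immunoglobulin A heavy chain on chromosome 12 (113254830 to 113260236), rose from 0.963 ± 0.112 FPKM in wild type to 33.3 ± 9.97 FPKM in the knockout (n = 2 each), and Gm21887, a predicted gene at the end of chromosome X (170009659 to 170019281), rose from 0 and 0.069 FPKM to 10.1 and 9.95 FPKM. Hist1h4m, a replication-dependent histone H4 gene on chromosome 13 (21811746 to 21812147), fell from 147 ± 13.9 FPKM to 10.7 ± 2.93 FPKM. The log2 changes were 4.10 (SE 0.21, limma adjusted p = 0.00945) for Igha, 3.41 (SE 0.14, adjusted p = 0.0083) for Gm21887 and -3.68 (SE 0.19, adjusted p = 0.00945) for Hist1h4m. These were 3 of 24535 rows tested, 1 of them among 10529 mRNA rows, 0 among 11971 lncRNA rows and 2 among 2035 other rows. At an unadjusted p below 0.05 there were 1314 rows (614 higher and 700 lower in the knockout), where 1227 would be expected by chance. The mRNA rows held 289 of these (187 higher and 102 lower) where 526 would be expected, and the other rows that are not lncRNA 333 (186 higher and 147 lower) where 102 would be expected. Of all rows tested, 30.9% had groups that did not overlap, against 33.3% by chance. All 3 calls were lost when either knockout library was left out (0 calls in each case) and when the filter was lowered to 0.1 FPKM or dropped (0 calls). Left-out wild-type libraries gave 12 calls without replicate 1 and 24 without replicate 2.

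**Figure D1:**
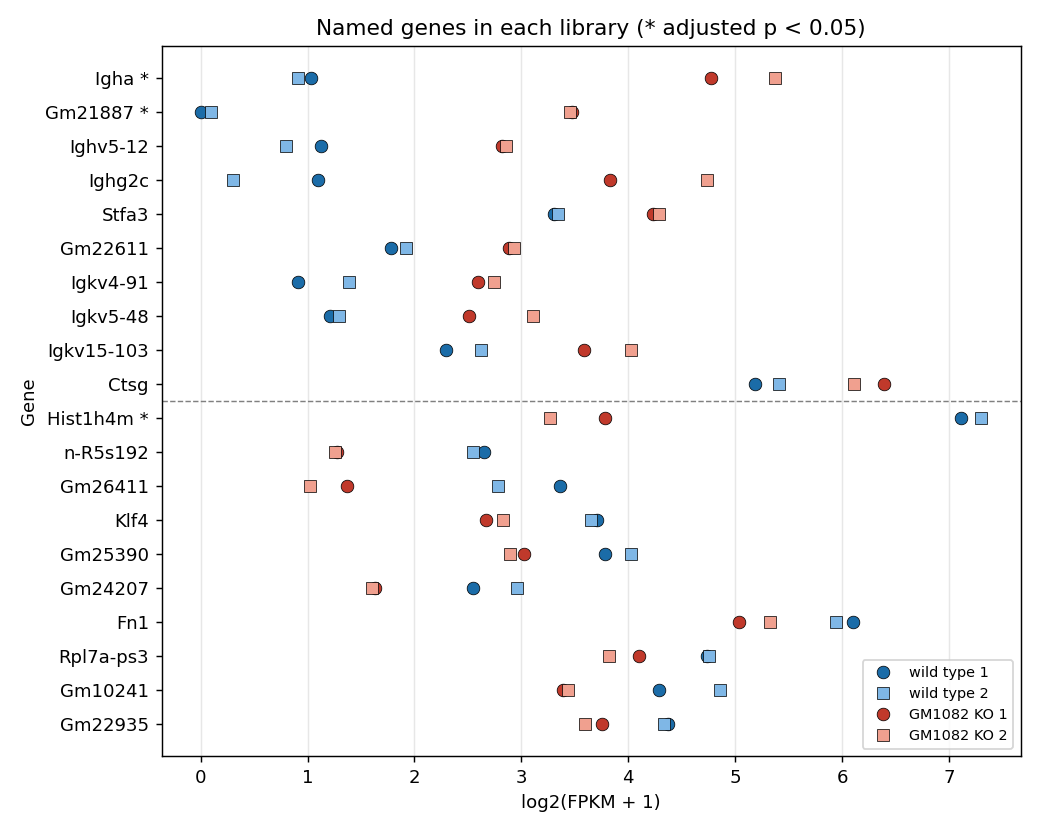
Level of each gene taken by the naming rule, as log2(FPKM + 1) on the horizontal axis, with 1 point per library: circles for replicate 1 and squares for replicate 2, blue for wild type and red for the knockout. Genes above the dashed line were higher in both knockout libraries and those under it lower; an asterisk marks Igha, Gm21887 and Hist1h4m, the 3 genes past an adjusted p of 0.05.

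Immunoglobulin genes made up 6 of the 10 higher genes that the naming rule took, and of these Igha alone passed. Ighg2c, the constant region of an immunoglobulin G heavy chain on chromosome 12 (113285325 to 113288932), stood at 1.15 and 0.237 FPKM in wild type and at 13.2 and 25.7 FPKM in the knockout (limma adjusted p = 0.203). The variable segments Ighv5-12, Igkv4-91, Igkv5-48 and Igkv15-103 had wild-type means of 0.965, 1.24, 1.38 and 4.54 FPKM and knockout means of 6.16, 5.37, 6.18 and 13.1 FPKM, with adjusted p between 0.142 and 0.371. Over all immunoglobulin rows, a group formed after the values were seen, 123 of 132 tested were higher in the knockout on average, with a median log2 change of 0.56 (0.89 without wild-type replicate 2). In 83 of them both knockout libraries lay above both wild-type libraries and in 2 below, where 33.3% would be separated by chance, and 72 were higher and 0 lower at an unadjusted p below 0.05. As a group they passed tests that are not independent evidence, since the group was formed on these libraries: camera (p = 1.36e-50, p = 0.0394 with an estimated correlation) and fry (p = 0.0424). Outside the naming rule, Ighm, the heavy chain of immunoglobulin M, was at 181 ± 50 FPKM in wild type and 188 ± 4.67 FPKM in the knockout, and Ighd, the heavy chain of immunoglobulin D, at 22.4 ± 10.4 and 42.1 ± 0.317 FPKM. The lambda constant region Iglc2 was at 17.6 ± 3.87 and 29.7 ± 1.75 FPKM, while Iglc3, another lambda constant region, overlapped between genotypes (10.8 ± 4.26 and 13.9 ± 0.584). Jchain, which joins polymeric immunoglobulins, was at 1.22 ± 0.25 and 9.83 ± 5.6 FPKM. Among the fixed lists, B cell markers as a whole did not pass (16 tested, 10 higher and 6 lower, camera adjusted p = 0.554). Adjusted over the list alone, 3 of these 16 passed, 1 higher and 2 lower. Igkc, the kappa constant region, was at 153 ± 39.8 FPKM in wild type and 329 ± 71.9 in the knockout. Vpreb1, part of the surrogate light chain of B cell precursors, was at 2.02 ± 0.338 and 0.909 ± 0.139, and Rag1, part of the recombinase of antigen receptor genes and outside the naming rule, at 8.21 ± 2.23 and 3.81 ± 1.31. Variable segments are short and resemble each other, so their values are uncertain.

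Neighbours of Gm21887 were higher too, without passing. The window from 100 kb before to 100 kb after Gm21887 (chromosome X, 169909659 to 170119281) held 7 tested rows, and each was higher in both knockout libraries than in either wild-type library. Mid1, a ubiquitin ligase gene whose annotated span (169685199 to 170005736) ends 5' of Gm21887 on the same strand, was at 0.698 ± 0.0824 FPKM in wild type and 2.43 ± 1.05 in the knockout (limma adjusted p = 0.672). Of the 5 higher lncRNAs taken by the naming rule, 4 lay in this window. NONMMUG046371.2 was at 0.0677 and 0.0676 FPKM in wild type and 5.61 and 10 FPKM in the knockout (adjusted p = 0.14). NONMMUG087042.1 was at 1.42 ± 0.182 and 7.01 ± 1.44 FPKM, and NONMMUG046370.2 at 0.031 ± 0.0263 and 2.64 ± 0.991 FPKM. NONMMUG096512.1, which lies within Gm21887, was listed at 0 in both wild-type libraries and at 3.44 and 9.94 FPKM in the knockout. The other higher lncRNA, NONMMUG096618.1 on chromosome Y (90740088 to 90740485), was at 0.198 ± 0.0932 and 9.83 ± 5.48 FPKM. The rows on chromosome X overlap Mid1 or Gm21887, and Mid1 has a pseudogene on chromosome Y, so reads may be shared among them and their values are uncertain.

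**Figure D2:**
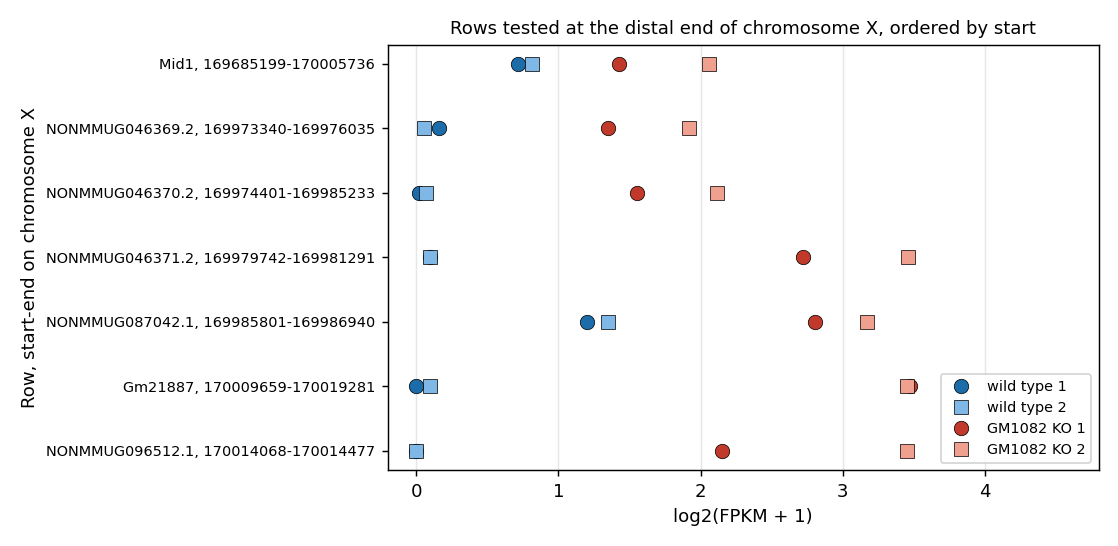
Level of the 7 tested rows of the window around Gm21887, ordered by start on chromosome X, as log2(FPKM + 1) on the horizontal axis with 1 point per library (blue wild type, red knockout, circles replicate 1, squares replicate 2). In every row both knockout points lie to the right of both wild-type points, and Gm21887 is the row past an adjusted p of 0.05.

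Among the lncRNAs, 0 of 11971 passed with limma, and 692 had an unadjusted p below 0.05 (241 higher and 451 lower) where 599 would be expected by chance. Without wild-type replicate 1 there were 3, and without wild-type replicate 2 there were 5. The 5 lower lncRNAs taken by the naming rule did not pass. NONMMUG068729.1 on chromosome 2 (148520918 to 148547613) was at 2.91 ± 0.189 FPKM in wild type and 0.494 ± 0.108 in the knockout (adjusted p = 0.237), and NONMMUG089162.1, within Atxn7l1 on chromosome 12, at 12.2 ± 0.172 and 5.49 ± 0.476 FPKM. NONMMUG032128.2 within Babam2 was at 4.43 ± 0.121 and 1.66 ± 0.028 FPKM, NONMMUG067396.1 on chromosome 2 at 6.53 ± 0.337 and 2.63 ± 0.488 FPKM, and NONMMUG073538.1 within Macf1 at 2.67 ± 0.113 and 0.773 ± 0.109 FPKM. Of 32 named long noncoding RNAs, 11 were matched by position and 7 tested, and the list did not pass (camera adjusted p = 0.308). Neat1, which builds nuclear paraspeckles, was at 66.2 ± 10.3 FPKM in wild type and 58.9 ± 4.71 in the knockout, and Gas5 at 9.28 ± 1.04 and 8.07 ± 0.881.

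The other named genes did not pass (limma adjusted p between 0.204 and 0.459). On the higher side, Stfa3, a stefin that inhibits cysteine proteases, was at 9.03 ± 0.175 FPKM in wild type and 18.2 ± 0.554 in the knockout. Ctsg, the granule protease cathepsin G, was at 38.4 ± 4.25 and 75.6 ± 10.3, and Gm22611 at 2.62 ± 0.246 and 6.5 ± 0.153. On the lower side, Klf4, a transcription factor of monocyte differentiation, was at 11.8 ± 0.358 FPKM in wild type and 5.75 ± 0.537 in the knockout, and Fn1, the matrix protein fibronectin, at 64.1 ± 5.25 and 35.5 ± 5.23. The remaining lower genes were the ribosomal protein pseudogene Rpl7a-ps3 (25.8 ± 0.22 and 14.7 ± 2.13 FPKM), Gm10241 (23.3 ± 6.73 and 9.65 ± 0.251) and several short genes. Of these, n-R5s192 was at 5.07 ± 0.314 and 1.41 ± 0.0237 FPKM, and Gm26411 at 7.59 ± 2.43 and 1.31 ± 0.39. Gm25390 was at 14 ± 1.79 and 6.77 ± 0.497, Gm24207 at 5.82 ± 1.37 and 2.07 ± 0.0349, and Gm22935 at 19.4 ± 0.366 and 11.8 ± 0.957. Hist1h4m itself belongs to a family with nearly identical coding sequences, and the other 10 Hist1h4 rows had higher means in the knockout. None of the 9 tested among these passed, and all 9 were higher with either alternative scaling too. Of them Hist1h4n, outside the naming rule, had the smallest p (415 ± 36.7 FPKM in wild type and 533 ± 13.6 in the knockout, limma adjusted p = 0.866). Whether reads moved between these copies and Hist1h4m was not tested.

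Of 43 gene lists tested with camera, 11 passed an adjusted p of 0.05, 9 higher and 2 lower in the knockout (7 and 4 with quantile normalization). Without knockout replicate 2 there were 19. With an estimated correlation 0 of the 43 passed (smallest adjusted p = 0.816, and 0 with an unadjusted p below 0.05). With fry, 0 passed for a shift to one side (smallest adjusted p = 0.57, 1 with an unadjusted p below 0.05) and 0 for change in either direction (smallest adjusted p = 0.129). Lists are therefore described below with their member values, and a member is said to have passed its list where its p was below 0.05 when adjusted over the list alone. None of the members of the 11 lists passed over all genes tested.

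Markers of granulocytes and progenitors lay higher in the knockout. Of 17 markers of mast cells, basophils and eosinophils, 16 were higher and 1 lower (median log2 change 0.54, camera adjusted p = 9.34e-10, adjusted p = 0.816 with an estimated correlation), and 4 passed adjusted over the list alone. These were the eotaxin receptor gene Ccr3 (7.5 ± 0.683 FPKM in wild type and 14.6 ± 2.42 in the knockout), the eosinophil ribonuclease Ear1 (3.81 ± 0.709 and 11.5 ± 5.49), the IgE receptor subunit Fcer1a (0.972 ± 0.26 and 2.15 ± 0.0758) and Il4 (1.56 ± 0.273 and 3.44 ± 1.05). All 20 neutrophil markers were higher (median 0.31, adjusted p = 3.13e-07, adjusted p = 0.816 with an estimated correlation), and 2 passed over the list alone, Ctsg and the myeloperoxidase gene Mpo (22.2 ± 4.76 and 42.9 ± 9.72 FPKM). Prtn3 (25.8 ± 2.15 and 48.3 ± 17.5 FPKM) and Elane (61.9 ± 6.26 and 133 ± 65.4), further proteases of primary granules, did not. Of 14 progenitor markers, 13 were higher (median 0.25, adjusted p = 5.83e-05, adjusted p = 0.816 with an estimated correlation) and 0 passed over the list alone, where 4 had an unadjusted p below 0.05. Among them, Mpo had the smallest p, Tal1 was at 2.39 ± 0.236 and 3.71 ± 0.0716 FPKM, Gfi1b at 2.23 ± 0.285 and 3.2 ± 0.0971, and Cd34 at 3.16 ± 0.761 and 4.59 ± 0.28. The progenitor list is not separate from the lists before it. It shares Mpo and Cebpe with the neutrophil markers and Kit and Gata2 with the markers of mast cells, basophils and eosinophils. Without knockout replicate 1 the neutrophil median turned to -0.074 (adjusted p = 0.85) and the progenitor list no longer passed (median 0.084, adjusted p = 0.15). Without knockout replicate 2 their medians were 0.79 and 0.38.

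Lists of sterol synthesis and of DNA replication were higher in the knockout by small amounts. All 23 genes of cholesterol biosynthesis and SREBP2 targets were higher (median 0.22, camera adjusted p = 3.45e-09, adjusted p = 0.816 with an estimated correlation), 14 of them without overlap (33.3% of genes are separated by chance, in either direction), and 0 passed over the list alone, where 3 had an unadjusted p below 0.05. The median was 0.12 without wild-type replicate 1 and 0.35 without wild-type replicate 2. Dhcr7, which makes cholesterol from its last precursor, was at 5.17 ± 0.902 FPKM in wild type and 7.34 ± 0.456 in the knockout, Pmvk at 16.5 ± 0.468 and 22.2 ± 3.8, Nsdhl at 10.8 ± 0.293 and 13.9 ± 1.33, and Fdps at 4.35 ± 0.579 and 5.66 ± 0.058. All 15 tested replication-dependent histones of the list, which does not hold Hist1h4m, the histone that fell, were higher (median 0.20, adjusted p = 0.000107, adjusted p = 0.816 with an estimated correlation), among them the linker histones Hist1h1e (143 ± 6.02 and 189 ± 15.4 FPKM), Hist1h1c (406 ± 27.9 and 489 ± 69.4) and Hist1h1b (347 ± 63.6 and 433 ± 70.1). Of 33 genes of DNA replication and S phase, 28 were higher (median 0.15, adjusted p = 0.00548, adjusted p = 0.824 with an estimated correlation), with Uhrf1 at 21.2 ± 4.49 and 26.8 ± 3.07 FPKM and Lig1 at 9.79 ± 1.44 and 11.9 ± 0.879. Adjusted over the list alone, 0 members of either list passed, where 1 histone and 0 S phase genes had an unadjusted p below 0.05. Without wild-type replicate 1 the S phase median turned to -0.027 and the histone median was 0.047 (adjusted p = 0.554 for both), and without wild-type replicate 2 they were 0.32 and 0.44. The S phase median was 0.26 without knockout replicate 1 and 0.022 without knockout replicate 2 (adjusted p = 0.589).

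Alternative activation and lysosome lists lay lower. Of 21 genes of alternative macrophage activation, 15 were lower and 6 higher (median -0.11, camera adjusted p = 0.00548, adjusted p = 0.816 with an estimated correlation), and 2 passed over the list alone, Klf4 and Fn1. Pparg, a nuclear receptor of lipid metabolism, was at 7.77 ± 0.435 FPKM in wild type and 5.19 ± 0.393 in the knockout, and Cd200r1 at 78.2 ± 8.24 and 57.8 ± 8.95. Of 32 lysosomal genes, 27 were lower (median -0.08, adjusted p = 0.0116, adjusted p = 0.816 with an estimated correlation) and 0 passed over the list alone, where 3 had an unadjusted p below 0.05. The cathepsins Ctsk (6.99 ± 0.077 and 4.48 ± 0.154 FPKM), Ctsa (66.3 ± 1.4 and 52.4 ± 0.0897) and Ctsc (112 ± 0.73 and 88.2 ± 11.6) and the membrane protein Lamp1 (224 ± 16.2 and 189 ± 14.3) had the smallest p. The alternative activation list no longer passed without wild-type replicate 1 (adjusted p = 0.0961), with a filter of 0.1 FPKM (adjusted p = 0.0592) or with no filter (adjusted p = 0.122), and its median was -0.20 without wild-type replicate 2 and -0.24 without knockout replicate 2. The lysosome median was -0.13 without knockout replicate 1, and that list did not pass without wild-type replicate 1, wild-type replicate 2 or knockout replicate 2 (adjusted p from 0.0758 to 0.157).

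Complement genes divided. Of 11 tested, 6 were higher and 5 lower (median 0.08, camera adjusted p = 0.0116, adjusted p = 0.816 with an estimated correlation), and 4 passed higher over the list alone. These were the C1q chains C1qa (9.78 ± 0.209 FPKM in wild type and 15.9 ± 1.82 in the knockout), C1qb (17.1 ± 1.35 and 23.6 ± 2.57) and C1qc (5.67 ± 0.419 and 9.79 ± 1.49), which start the classical pathway, and Cd55 (5.91 ± 1.51 and 9.49 ± 0.176), which restrains complement on the cell surface. Monocyte markers passed narrowly (13 tested, 9 higher and 4 lower, median 0.22, adjusted p = 0.0475, adjusted p = 0.816 with an estimated correlation) with members on both sides. Ms4a4c passed over the list alone (6.15 ± 0.907 and 12.1 ± 1.69 FPKM), and Plac8 was at 51 ± 0.184 and 66.5 ± 2.88. Vcan (24.8 ± 2.78 and 18.8 ± 2.52) and the chemokine receptor gene Ccr2 (57.6 ± 3.7 and 40.1 ± 12.5) lay the other way. Of 23 antioxidant and NRF2 target genes, 19 were higher (median 0.07, adjusted p = 0.0337, adjusted p = 0.816 with an estimated correlation) and 0 passed over the list alone, where 0 had an unadjusted p below 0.05, with Gstm1 at 49.1 ± 2.27 and 56.1 ± 1.4 FPKM. The complement median was -0.023 without knockout replicate 1 (adjusted p = 0.189), -0.040 with a filter of 0.1 FPKM (adjusted p = 0.112) and 0.22 without knockout replicate 2. That list did not pass with no filter (adjusted p = 0.153) or on ranks (adjusted p = 0.269). The monocyte list lost its call in 10 of 17 alternatives. Among them were the fits without knockout replicate 1 or wild-type replicate 2 (medians 0.075 and 0.039, adjusted p = 0.344 and 0.363), both scalings (adjusted p = 0.053 and 0.108), both lower filters (adjusted p = 0.0994 and 0.153), ranks (adjusted p = 0.122) and Ensembl rows alone (adjusted p = 0.112). The antioxidant list lost its call in 8 of 17. Among them were the fits without any single library but knockout replicate 2 (adjusted p between 0.0916 and 0.363), quantile normalization (adjusted p = 0.152), a filter of 0.1 FPKM (adjusted p = 0.0557) and Ensembl rows alone (adjusted p = 0.095).

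**Figure D3:**
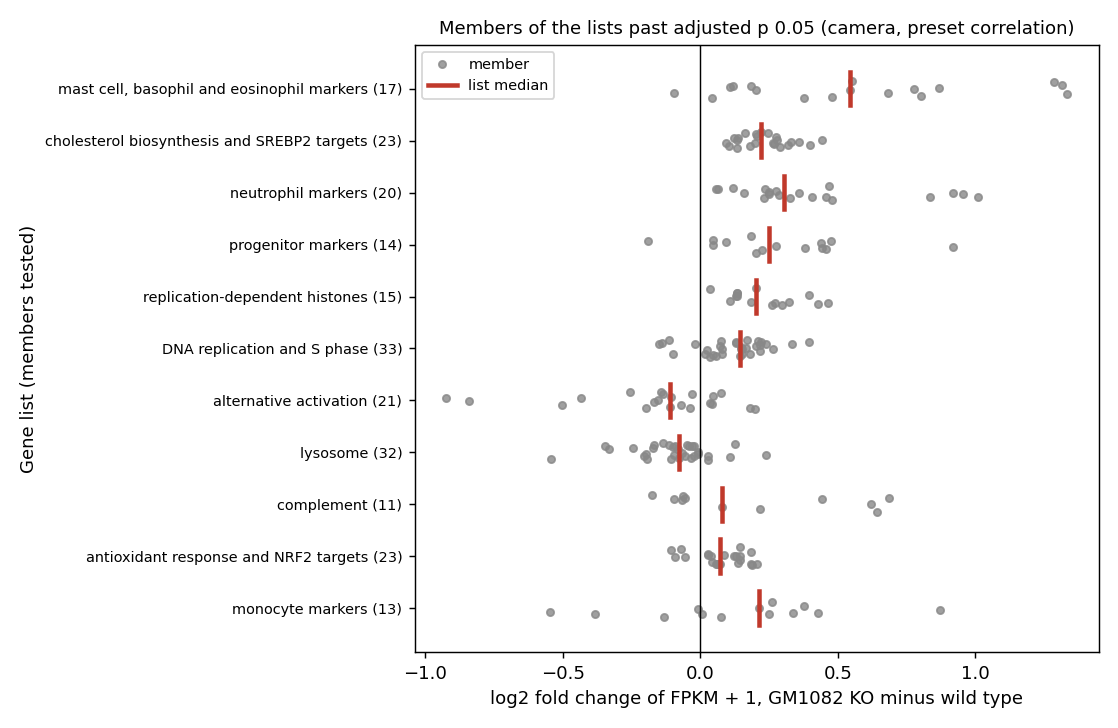
Log2 fold change of FPKM + 1, knockout minus wild type, of each tested member (grey points, spread vertically for legibility) of the 11 lists past an adjusted p of 0.05 by camera at a preset correlation, with the list median as a red bar. Medians run from -0.11 for alternative activation to 0.54 for mast cell, basophil and eosinophil markers.

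The other 32 lists did not pass (camera adjusted p between 0.0516 and 0.971). Macrophage identity genes did not differ as a list (26 tested, 10 higher and 16 lower, adjusted p = 0.279), with the lysozyme gene Lyz2 at 1921 ± 19.8 FPKM in wild type and 1479 ± 150 in the knockout and Trem2 at 11.6 ± 0.103 and 9.38 ± 0.27. Type I interferon-stimulated genes (33 tested, median 0.09, adjusted p = 0.052) and glycolysis genes (21 tested, median 0.08, adjusted p = 0.0516) lay just above the threshold. With an estimated correlation their camera adjusted p was 0.827 and 0.816, and 0 members of either had an unadjusted p below 0.05. Among 21 cytokines and chemokines of inflammation (adjusted p = 0.102), Ccl2 passed over the list alone at 6.75 ± 0.225 and 11.7 ± 1.74 FPKM, and Ccl5 was at 8.3 ± 0.0731 and 12.2 ± 0.904. Among 15 LXR targets (adjusted p = 0.886), Apoe, the lipid carrier apolipoprotein E, passed over the list alone at 5.52 ± 0.171 and 9.91 ± 0.0172 FPKM. Among 8 T and NK cell markers (adjusted p = 0.0863), the surface glycoprotein gene Thy1 passed over the list alone at 14.1 ± 1.34 and 24.6 ± 1.73 FPKM. Over all genes tested, Ccl2, Apoe and Thy1 did not pass (limma adjusted p = 0.537, 0.433 and 0.445). The adjustment over a list alone does not account for the number of lists. Genes of MHC class II presentation (12 tested, adjusted p = 0.971) and ribosomal proteins (47 tested, adjusted p = 0.521) had medians of -0.0077 and 0.0015.

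Libraries resembled each other about as much between as within genotypes. Across the 24535 tested genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.976 between the wild-type libraries and 0.972 between the knockout libraries. Between genotypes it ran from 0.970 to 0.975, with a mean of 0.972, so the mean within genotypes (0.974) exceeded that between them by 0.0023.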

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

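The tests on Ensembl rows alone and NONCODE rows alone were chosen after the data were seen. Igha, Gm21887 and Hist1h4m passed with limma in 7 of the fits that kept all 4 libraries and changed the pseudocount, scaling, variance model, the filter to 5 FPKM or the block, and with Ensembl rows alone. The count fell to 0 of 43586 rows with a filter of 0.1 FPKM (2365 at an unadjusted p below 0.05) and to 0 of 62046 rows with no filter (3298 at an unadjusted p below 0.05). Of the mRNAs 0 passed in both (341 and 429 at an unadjusted p below 0.05). At an unadjusted p below 0.05 there were 1314. Leaving out 1 library gave from 0 to 24 genes, 0 to 1 mRNAs and 0 to 5 lncRNAs, with 1102 and 1693 genes at an unadjusted p below 0.05 in the fits without a knockout library, where 0 passed; the lone library of a genotype is there assumed to vary like the other genotype, with 1 residual degree of freedom. With the replicate number as a block, 6 genes and 2 lncRNAs passed, and the fit with a pseudocount of 0.1 gave 1 lncRNA. The titles do not say that the numbers pair libraries, so they were not read as pairs. Same-numbered libraries deviated together little across all genes (r = 0.0509), which does not exclude a shared difference in some genes. The split by replicate number gave 1444 genes at an unadjusted p below 0.05 and 19 lists, against 1314 and 11 for genotype. The difference of Gm1082, 0.02 on the log2 scale, was 0.16 with a pseudocount of 0.1 and between -0.02 and 0.06 with a library left out. The number of lists, 11, was 7 with a filter of 0.1 FPKM, 0 with an estimated correlation, 0 with fry (0 and 1 at an unadjusted p below 0.05), and from 10 to 19 with a library left out. The direction turned for DNA replication and S phase without wild-type replicate 1 (medians with a library left out from -0.027 to 0.32) and for neutrophil markers without knockout replicate 1 (from -0.074 to 0.79). The complement median turned without knockout replicate 1 (-0.023) and with a filter of 0.1 FPKM (-0.040), where the test kept its direction and did not pass. The direction also turned for 6 genes that passed in neither fit, here with their lowest and highest log2 change with a library left out: H2-Ab1 (-0.0023 to 0.28), Ddit4 (-0.14 to 0.74) and mt-Cytb (-0.30 to 0.078) without knockout replicate 1, mt-Nd2 (-0.17 to 0.55) and Hsp90aa1 (-0.0059 to 0.44) without knockout replicate 2, and Cd209a (-0.90 to 0.0010) without wild-type replicate 2. The cause of these changes was not tested. Of the alternatives for the 11 lists, 136 kept the direction of the test and the side of the threshold, 49 kept the direction alone and 2 turned. Of those for the genes named or listed, 1741 kept both, 13 newly passed, 12 no longer passed and 6 turned. The excess of within-genotype over between-genotype correlation, 0.0023, ran from 0.0029 to 0.0044 in its 3 alternatives. Depth limits the rows near 1 FPKM most, where 1 kb of gene rests on 17.7 to 19.1 fragments.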

Other observations

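The tests on B-lineage markers, on chromosomes X and Y, and on granulocyte markers without knockout replicate 1, and the count of splits for genes, were chosen after the results were seen. Some single genes were looked at after their values were seen. Rag2, partner of Rag1, was at 0.987 ± 0.248 FPKM in wild type and 0.384 ± 0.156 in the knockout (n = 2 each), under the filter, and Igll1, part of the surrogate light chain, at 2.17 ± 0.936 and 0.928 ± 0.12, not past an adjusted p of 0.05 with limma. Summed immunoglobulin FPKM was 651 and 941 in wild-type replicates 1 and 2 and 1272 and 1467 in knockout replicates 1 and 2. The eosinophil granule genes Prg2 (24.9 and 24.4 FPKM in wild type, 98.2 and 38.5 in the knockout) and Epx (3.26 and 3.92, 19.6 and 5.48) were highest in knockout replicate 1, as were the neutrophil granule genes Ngp (773 and 755, 1530 and 732), Ltf (98.1 and 113, 197 and 88.7) and Camp (36.8 and 42, 104 and 29). Of the 6 sex-specific genes listed, 0 had a row in the table used here, and the row at the position of Xist was between 0 and 0.00314 FPKM in the 4 libraries, so sex was not settled.

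Immunoglobulin transcripts of switched classes (Igha, Ighg2c) and of the unswitched class of Ighd were higher in both knockout libraries, while those of Ighm overlapped. B-lineage cells of every stage in larger number would raise the other B cell markers as well, but the median log2 change of the 14 such markers outside immunoglobulin genes was 0.044 (SE of the median 0.16). A candidate explanation, antibody-secreting cells, was tested with 12 markers listed before the test; for the 9 measured, the median log2 change was 0.0040, at the 46.3 percentile of 10000 random sets matched on mean expression, which decides neither way. Of the 9, 5 were higher on average, but 0 were higher in both knockout libraries than in either wild-type library. Among abundant ones, Tnfrsf13b was at 34 ± 0.0747 FPKM in wild type and 33.3 ± 0.728 in the knockout, Pou2af1 at 28.1 ± 5.24 and 24.7 ± 3.29, and Txndc5 at 14.6 ± 1.27 and 16.8 ± 2.02. Among less abundant ones, Mzb1 was at 3.94 ± 0.571 and 3.4 ± 1.45, Sdc1 at 3.4 ± 1.21 and 3.91 ± 0.77, Prdm1 at 2.28 ± 0.234 and 2.28 ± 0.116, and Fkbp11 at 1.1 ± 0.11 and 1.32 ± 0.314. Jchain, described above with the immunoglobulin genes and not among the 9, was at 1.04 and 1.39 FPKM in wild type and 5.87 and 13.8 in the knockout. A difference due to the genotype stays open and untested.

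Transcripts at the distal end of chromosome X were higher in both knockout libraries. In the window around Gm21887, 7 of 7 tested rows were higher at an unadjusted p below 0.05, but the window was set around the called gene and its rows overlap Mid1 or Gm21887, so a one-sided hypergeometric exact test over it (p = 5.94e-12) decides nothing. Reads moved from the related region on chromosome Y would lower the rows there. Of the 3 tested rows there, 2 were higher in the knockout at an unadjusted p below 0.05 with limma. The other, Mid1-ps1, was at 1.85 ± 0.0585 FPKM in wild type and 1.43 ± 0.229 in the knockout. The summed level there was higher by 11.9 FPKM in the knockout, but NONMMUG096618.1 alone rose from 0.198 to 9.83 FPKM. FPKM of rows of unlike length do not add up to reads, so the sum does not settle whether reads moved. Reads shared between the regions, which could raise both, were not tested for. A local difference in sequence or copy number between the chromosomes of the mouse lines stays open without a test that bears on it, and cannot be told apart from an effect of the genotype, because each line is 1 group and the labels give no strain. A related check was fixed before its result was seen. The 177 tested rows within 5 Mb of Gm1082 on chromosome 7 had a median absolute limma t of 0.55. This was at the 4.0 percentile of 20640 windows of equal size. A median that is not raised argues against carried-along sequence from another strain shifting most tested rows there. The rank itself may reflect the mix of rows, since the windows were matched on the number of rows alone. Over all tested rows, 289 of 10529 mRNA rows and 333 of 2035 other rows had an unadjusted p below 0.05 with limma. Of the 177 rows, 5 had an unadjusted p below 0.05 with limma and 0 passed an adjusted p of 0.05. A median hardly responds to changes in a few rows, so carried-along sequence that changed only a few genes stays open. Prodh2, next to Gm1082 and under the filter, was not part of the check.

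Neutrophil markers and markers of mast cells, basophils and eosinophils were higher in the knockout. For neutrophil markers, a larger share of such RNA in a single culture is a candidate explanation, since the list median was -0.074 without knockout replicate 1 and 0.79 without knockout replicate 2. Of the 20 members, 7 lay above both wild-type libraries in both knockout libraries, where 33.3% would do so by chance if knockout replicate 1 alone were raised, among them Ctsg (35.4 and 41.4 FPKM in wild type, 82.9 and 68.3 in the knockout) and Mpo (18.8 and 25.6, 49.8 and 36). For mast cell, basophil and eosinophil markers a single library is argued against as the whole cause, since the median stayed at 0.42 without knockout replicate 1. That median rests on knockout replicate 2 alone, and the members vary together (estimated correlation 0.60), so they do not stand in for replicates. Over all 4 libraries the list had a camera adjusted p of 0.816 with an estimated correlation. An effect of the genotype on these cells stays open and untested.

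The 4 libraries allow 3 splits into pairs, too few for a share under 0.05. For genes past an adjusted p of 0.05, the real split gave 3 and the highest other 0, and 1 of the 3 splits gave at least 3. At an unadjusted p below 0.05 the real split gave 1314 genes, the split by replicate number 1444 and the remaining split 993. For lists, the real split gave 11 and the highest other 19, and 2 of the 3 splits gave at least 11. The split with 19 lists is the one by replicate number, which sets replicate 1 of both genotypes against replicate 2 of both. A difference shared by same-numbered libraries therefore stays open.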
